A study of Mus musculus with 4 samples.

How the data were processed

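Per the labels, tumours of the implanted line PDA.69 were digested, dead cells were removed with a kit, and 10x Genomics 3' single-cell libraries were made from pools of mice, 2 libraries labelled WT and 2 labelled SAA_KO. The deposited matrices hold raw UMI counts per gene and barcode, made with Cell Ranger 6.1.2 per the file headers; the submitters' processing notes name Cell Ranger, Seurat 4.3.0, R 4.2.2 and the build mm10. Whether doublets were removed before deposit is not given in the sources used here. The series' design text speaks of mice with a liver deletion of Stat3, while the sample labels name serum amyloid A genotypes; the sample labels were followed. A deposited table of counts that joins the 4 libraries holds 20907 genes and 49808 cells, which are the barcodes with at least 100 detected genes, and of 20894 gene symbols found in the matrices 18546 had equal totals and 0 a higher total in the table. It was used for that comparison only. Gene positions come from GENCODE mouse release 21 (mm10), which holds 32158 of the 32285 gene IDs (99.6%).

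Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 42271 cells of 50273 barcodes. Scrublet, as built into scanpy 1.11.5, scored doublets per library with an expected rate of 0.8% per 1000 cells. Its automatic thresholds called 122, 0, 106 and 226 cells, so a score of 0.25 was used for each library, and clusters with over 30% of such cells were left out too. This removed 3.54, 3.48, 3.66 and 4.57% of cells and kept 40658. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with Leiden at a resolution of 1.0 (leidenalg 0.10.2, igraph 0.11.9, anndata 0.12.19, Python 3.11.15, seed 0). This gave 41 clusters, and a resolution of 2.0 gave 62. A cluster took a class name from fixed markers among its 10 genes of highest fold against cells of other classes (detected in at least 25% of its cells, 0.1 added per 10000), with at least 3 markers detected. The names cover 30 clusters, 20 classes and 36934 cells, and each is used in the sense of a cluster like that type. Unnamed cells held 8.75, 9.64, 8.19 and 10.3% of each library, among them cluster 5 (5.27, 5.49, 5.07 and 6.70%) and cluster 12 (2.75, 2.63, 2.74 and 2.71%), which had few UMIs. Barcodes shared between libraries numbered 152 for WT replicate 1 and SAA_KO replicate 1 and 41 to 48 for other pairs, and 626 kept cells carry one.

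Counts were summed per library over all kept cells and per class, for 17 classes with at least 25 cells in each library, and tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood F-tests, two-sided, after filterByExpr and TMM scaling, with Benjamini-Hochberg adjustment over the genes of each fit and a threshold of 0.05. CPM uses TMM-scaled library sizes. DESeq2 1.42.0 was an alternative. Shares of cells were tested with edgeR on cell numbers with the library's kept cells as offset. A set of 42 fixed lists, covering interferon and inflammatory responses, lymphocyte and myeloid functions, stroma, metabolism, stress and signs of free RNA, was tested with camera of limma 3.58.1 at a preset correlation of 0.01 over 18 fits and 620 pairs with at least 5 tested genes; 2 lists had too few tested genes in every fit. Camera with an estimated correlation and fry were alternatives. The difference between neutrophils and monocyte-macrophage cells was tested in one edgeR fit with the library as a block. The p-values of edgeR and DESeq2 measure the spread between libraries, each a pool of mice. Those of camera at the preset correlation compare the members of a list with the other genes, so they measure the spread over genes. Intervals and floors (3 counts per library) cover counting error only.

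The tests, markers, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the 4 serum amyloid A genes, up to 5 genes each way per class (10 in the sums over all cells) among those past the threshold whose libraries do not overlap between groups, up to 5 of smallest p as values where fewer passed, a fixed panel per kind of cell, and up to 4 members of a list. Chosen after seeing the data were the doublet score and the 30% rule, the cluster names, the joint monocyte-macrophage class, the fold against cells of other classes, cycling cells as classes of their own, the 2 clusters unnamed for few UMIs, a share test with no trend of the spread over class size, and 4 alternatives: automatic doublet thresholds, shared barcodes left out, interferon-led clusters 19, 30 and 39 left out, and cycling CD8 T cells joined to the CD8 T cells. By the fold against all other cells, tumour cluster 2 held no tumour marker among its top genes and cluster 7 none by either, so tumour clusters are also given by number.

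The fits were tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn only from those with enough expected UMIs in the smallest library. The spread of each gene was the one edgeR had estimated, drawn towards that of other genes. The rates therefore do not cover genes of low counts and may overstate what the tests find. EdgeR recovered 61% and 82% of them in the sums over all cells (17154 genes), 77% and 96% in monocyte-macrophage cells (12595 genes), 64% and 98% in neutrophils (10224 genes), and 57% and 96% in CD8 T cells (6699 genes), with 32, 22, 17 and 4 unchanged genes called. A class share changed 4-fold, at a dispersion of 0.01, was found in 20 of 20 draws, with 2 other classes called. That dispersion was set and not taken from the data, where log2 share changes had an SE of 0.24 (tumour cells) to 1.25 (acinar cells). The draws therefore do not show what the share test can find in these libraries.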

Results

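The series measured gene expression in single cells of implanted pancreatic tumours. The tumours grew from PDA.69, a line derived from a genetically engineered mouse model of pancreatic ductal adenocarcinoma (KPC) and chosen, per the labels, for its few infiltrating T cells. Serum amyloid A proteins are acute-phase proteins that the liver releases in inflammation, and the series title concerns their release by hepatocytes and escape of such tumours from immunity. The comparison asks how the cells of tumours grown in mice lacking serum amyloid A genes (labelled SAA_KO) differ from those of tumours grown in wild-type mice (labelled WT). Per the labels, 4 mice were pooled to 2 libraries per condition, so n = 2 libraries in each group. The files hold 12695 and 11301 barcodes in the libraries labelled WT (replicates 1 and 2) and 13515 and 12762 in those labelled SAA_KO, with 104812338, 109776673, 96745221 and 103754278 unique molecular identifiers (UMIs). After filters, 10622, 8768, 11268 and 10000 cells were kept, with a median of 3225.5, 5019.5, 2574 and 4317 UMIs per cell. Values for single libraries are given in this order throughout, in CPM (UMIs scaled to a common library size) for genes. Fits without 1 library leave a lone library in its group. Within classes they called more genes than all 4 libraries together, so passing in them is weak support.

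The serum amyloid A genes were read first, as a check of the labels. Saa2, which encodes an acute-phase serum amyloid A protein (ENSMUSG00000057465, mm10 chromosome 7, 46751790 to 46754313, plus strand), had 14 and 5 UMIs in the libraries labelled WT and 1568 and 1310 in those labelled SAA_KO. This is the opposite of what the labels would give if the counted part of the gene were deleted. A 3' tag that lies outside the deleted part checks nothing, and the deleted part is not given in the sources used here. For that reason groups are named by their labels, and every direction below is that of the libraries labelled SAA_KO against those labelled WT. The Saa2 log2 fold change in the sums over all cells was 7.33 (SE 0.38, n = 2 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.141), and without WT replicate 2 it was 6.75 with an adjusted p of 0.0371 by the same test. Saa1, its near-identical neighbour (ENSMUSG00000074115, 46740497 to 46742980, minus strand), had 1, 27, 53 and 75 UMIs (log2 fold change 2.30, SE 1.00; 5.90 without WT replicate 2 and 1.38 without WT replicate 1). Reads of this pair can be assigned to either copy, so the split between them is uncertain. Saa3, which macrophages and fibroblasts make in inflammation (ENSMUSG00000040026, 46711998 to 46715700, minus strand), had 12545, 10686, 3591 and 1682 UMIs (log2 fold change -2.02, SE 0.40), which did not pass the test. Saa4 (ENSMUSG00000040017) had 0 UMIs in all 4 libraries, which allows up to 3 UMIs in each.

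**Figure D1:**
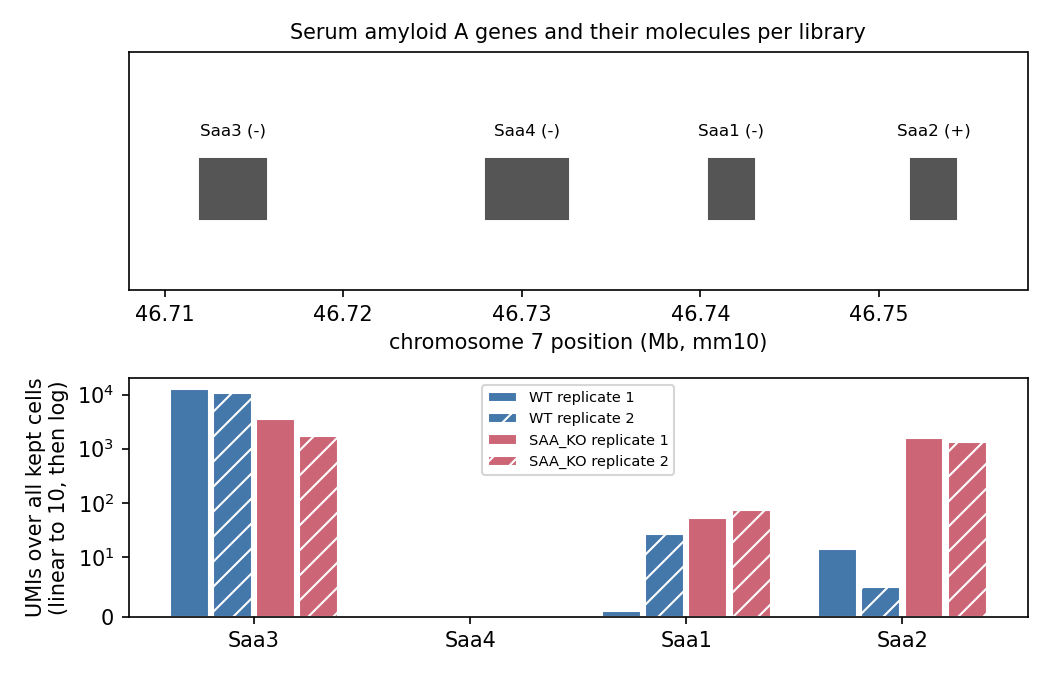
Positions of Saa3, Saa4, Saa1 and Saa2 on mouse chromosome 7 (mm10), above bars of their UMIs over all kept cells in each of the 4 libraries, on an axis linear to 10 and then logarithmic. Saa2 holds 14 and 5 UMIs in the libraries labelled WT and 1568 and 1310 in those labelled SAA_KO.

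Within cell classes, the Saa2 transcript passed the test in 6 classes of immune cells, higher in the libraries labelled SAA_KO. In each of the other tested cell classes, too, both libraries labelled SAA_KO lay above both labelled WT. In several of these the low-count filter left Saa2 out, so its change was not tested there. Among them were regulatory T cells (0, 0, 30.8 and 20.1 CPM), B cells (0, 0, 23.4 and 14.1) and CD8 T cells (0, 0, 11.3 and 13.5). In neutrophils it stood at 0.641 and 0 CPM in the libraries labelled WT and at 102 and 99.8 in those labelled SAA_KO, from 3 against 728 UMIs, a ratio of 235 (95% counting interval 80.0 to 1140). In monocyte-macrophage cells it stood at 0.495, 0, 57.2 and 38.9 CPM, a log2 fold change of 7.62 (SE 0.48). The ratio in cDC2 cells was 79.8 (95% counting interval 26.98 to 390, from 3 against 233 UMIs). Against groups with no UMI, taken at 3 counts per library, Saa2 was at least 12.99-fold higher in cycling macrophages, at least 12.01-fold in cDC1 cells and at least 8.76-fold in mature dendritic cells. All 6 classes passed in edgeR, with adjusted p from 5.6e-07 in neutrophils to 0.00545 in monocyte-macrophage cells (quasi-likelihood test, Benjamini-Hochberg), while DESeq2's Wald test did not call cDC2 (adjusted p = 0.765) or mature dendritic cells (0.0570), and cycling macrophages did not pass in edgeR without WT replicate 1 (0.993). That library held all Saa2 UMIs of the libraries labelled WT in neutrophils, monocyte-macrophage and cDC2 cells, and without it the fitted log2 fold changes there were 11.27, 12.44 and 10.06 (7.70, 7.62 and 6.23 with it). The tumour cells, which carry the genome of the implanted line, held 0.890 and 0.709 CPM in the libraries labelled SAA_KO against 0 and 0 (at least 11.3-fold), which did not pass (edgeR adjusted p = 0.881). In fibroblasts Saa2 stood at 0, 1.27, 35.4 and 19.8 CPM (log2 fold change 4.93, SE 0.61; edgeR adjusted p = 0.459), and it passed without SAA_KO replicate 1 (0.00304) or SAA_KO replicate 2 (0.0414), while without WT replicate 2 the value was 9.14 (0.465).

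Saa3 went apart between myeloid classes. In neutrophils it rose from 73.1 and 53.5 CPM in the libraries labelled WT to 227 and 134 in those labelled SAA_KO (log2 fold change 1.51, SE 0.23; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0363). In monocyte-macrophage cells it stood at 668, 250, 101 and 52.4 CPM, a log2 fold change of -2.59 (SE 0.47; edgeR adjusted p = 0.287) that passed without WT replicate 2 (-3.13, adjusted p = 0.00247) and was -1.72 without WT replicate 1. The difference of the 2 fold changes was itself tested and was 4.06 on the log2 scale (SE 0.21; edgeR adjusted p = 7.7e-11). It was among 15 of 12859 genes that passed that test. The insulin genes Ins2 (5.95) and Ins1 (5.78), named after their values were seen, had larger differences, which rest on WT replicate 2: both together stood at 0.00944, 5.47, 0.0228 and 0.0208 UMIs per monocyte-macrophage cell and at 0.00317, 0.0285, 0.0105 and 0.0144 per neutrophil. In monocyte-macrophage cells their log2 fold changes were -6.63 and -6.76 (edgeR adjusted p = 0.9998 for both), 1.01 and 1.72 without WT replicate 2, and past the threshold without WT replicate 1 (edgeR adjusted p = 3.0e-07 and 6.8e-08). In fibroblasts Saa3 stood at 1084, 1584, 487 and 112 CPM (-2.17, SE 0.57), in tumour cells at 6.12, 3.72, 2.34 and 1.25 (-1.45, SE 0.35) and in cycling tumour cells at 5.09, 3.29, 1.15 and 0.870 (-2.04, SE 0.32), none of which passed in edgeR. The value in fibroblasts was -3.58 without SAA_KO replicate 1 and -1.47 without SAA_KO replicate 2. Each of these 3 passed without SAA_KO replicate 1 (adjusted p = 2.6e-06, 0.0255 and 0.00707), and the last also without SAA_KO replicate 2 (0.0114).

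**Figure D2:**
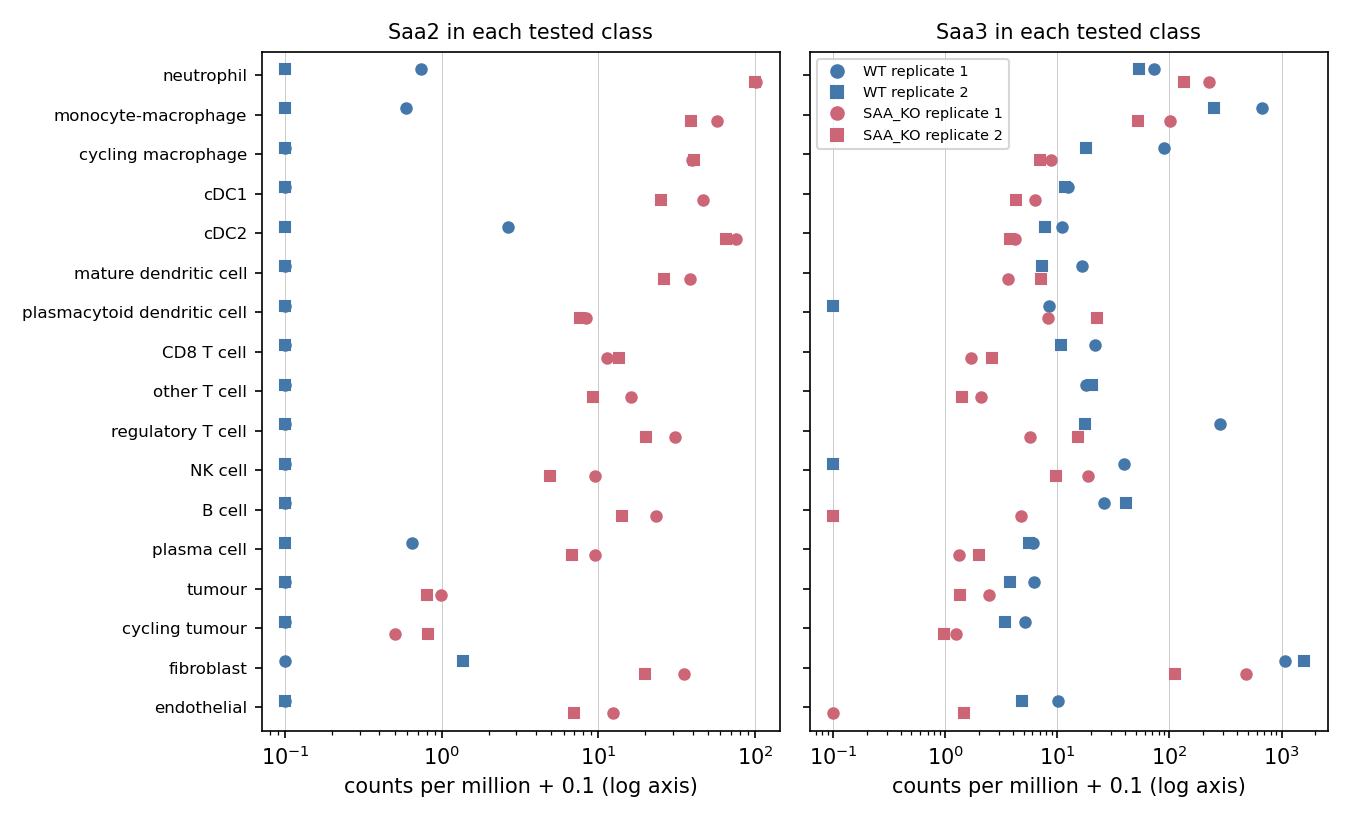
CPM of Saa2 (left) and Saa3 (right) in each of the 17 tested cell classes, 1 point per library, with 0.1 added on a log axis. In neutrophils Saa2 lies at 102 and 99.8 CPM and Saa3 at 227 and 134 in the libraries labelled SAA_KO, and Saa3 in monocyte-macrophage cells lies at 101 and 52.4 against 668 and 250 in those labelled WT.

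The tumours were rich in myeloid cells. Neutrophils took 29.7, 16.4, 32.1 and 13.2% of kept cells, monocyte-macrophage cells 22.94, 24.98, 19.04 and 26%, and tumour cells 16.64, 16.20, 15.96 and 15.61%. CD8 T cells, the killer lymphocytes, took 1.12 and 1.77% in the libraries labelled WT and 2.07 and 4.23% in those labelled SAA_KO, or 1.44% ± 0.458 against 3.15% ± 1.53 (SD, n = 2 each). Their log2 fold change was 1.12 (SE 0.50), and cycling CD8 T cells, at 0.0659, 0.1711, 0.1597 and 0.35%, had 1.11 (SE 0.68). Other T cells held 2.44, 3.83, 3.18 and 4.62%, regulatory T cells 1.34, 2.10, 1.59 and 1.36%, and natural killer (NK) cells 0.960, 0.981, 0.550 and 0.920%. The 3 clusters of tumour cells outside the cycle, by number 2, 7 and 9, held 7.75, 8.34, 6.24 and 6.97%, then 5.05, 4.61, 6.28 and 4.79%, then 3.84, 3.25, 3.43 and 3.85%. Of 20 classes, 0 passed 0.05 in edgeR's quasi-likelihood test on cell numbers (Benjamini-Hochberg adjusted p = 0.969 for each), and 0 lay at an unadjusted p under 0.05. No other tool was run on the shares, and an exact permutation of 2 against 2 libraries cannot go below p = 0.333. The CD8 T cell log2 fold change was 0.52 without SAA_KO replicate 2 and 1.55 without SAA_KO replicate 1. Acinar cells of the host pancreas held 0.989, 1.46, 0.124 and 1.88%, and without SAA_KO replicate 2 they passed (log2 fold change -3.29, edgeR adjusted p = 0.00306).

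**Figure D3:**
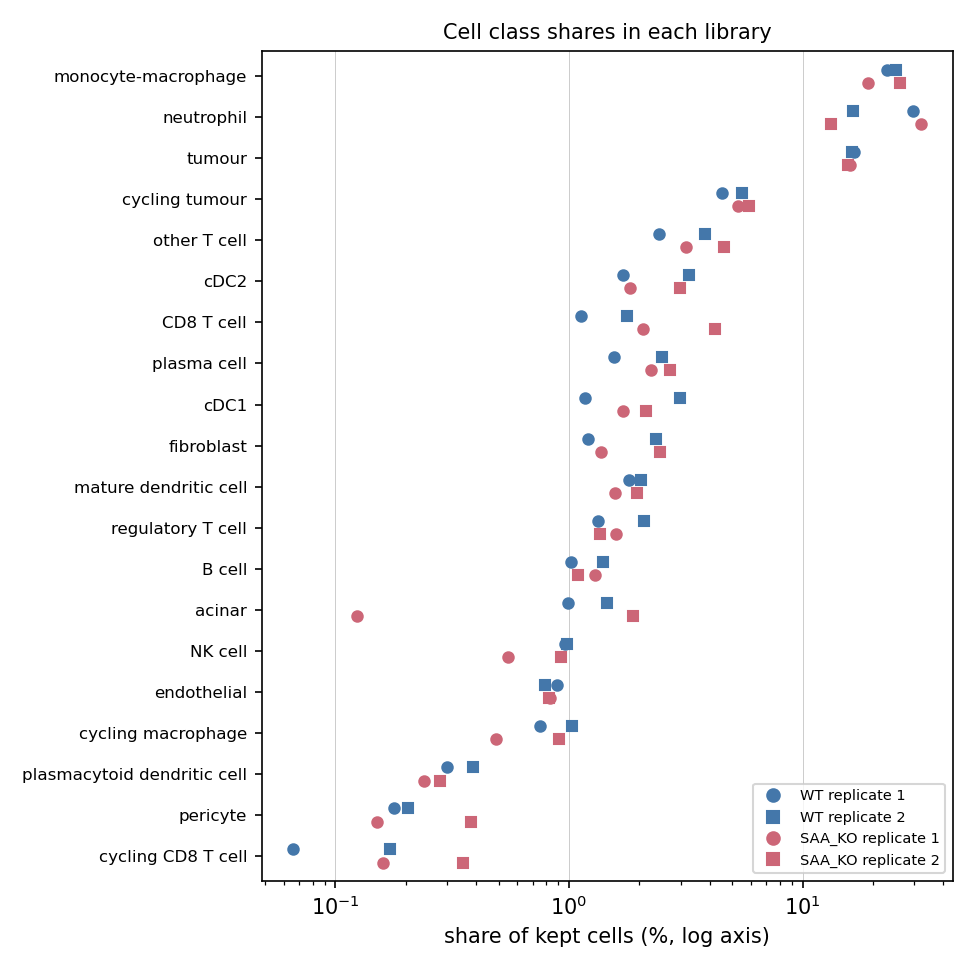
Share of kept cells in each cell class, in percent on a log axis, 1 point per library. CD8 T cells lie at 1.12 and 1.77% in the libraries labelled WT and at 2.07 and 4.23% in those labelled SAA_KO, and neutrophils differ more between libraries of a group (13.2 and 32.1%) than between groups.

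In the sums over all cells, which move with the mix of cell types, 0 of 17371 genes passed in edgeR (quasi-likelihood test, Benjamini-Hochberg), 340 lay at an unadjusted p under 0.05, and DESeq2's Wald test called 28 genes, 8 higher and 20 lower. The genes with the smallest p after Saa2 are given as values. Tff3, a secreted mucosal repair peptide of epithelia, stood at 8.19, 7.71, 1.81 and 1.84 CPM (log2 fold change -2.12, SE 0.12; edgeR adjusted p = 0.141). Ighm, the heavy chain of immunoglobulin M, stood at 129, 114, 36.5 and 30.9 CPM (-1.85, SE 0.12; edgeR adjusted p = 0.151). Igkv5-43, a light chain variable segment, stood at 0.725, 0.678, 3.03 and 2.72 CPM (2.03, SE 0.19). Rsad2, an antiviral gene that interferon switches on, stood at 21.3, 17.3, 7.69 and 7.95 CPM (-1.30, SE 0.13). Without WT replicate 2 the count was 2 genes.

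Tests within classes gave 39 calls for 30 distinct genes in 10 of 17 classes, 11 higher and 28 lower in the libraries labelled SAA_KO (edgeR quasi-likelihood test, Benjamini-Hochberg within each class, 0.05). Among them were serum amyloid A genes (7 calls higher), genes of the type I interferon response (6 calls lower), heat shock genes (3 calls lower), and chemokines and calprotectin genes that went either way. DESeq2 called 89. Without 1 library the total was 2.0e+02 (WT replicate 1), 374 (WT replicate 2), 509 (SAA_KO replicate 1) or 518 (SAA_KO replicate 2), and 20 of the 39 calls held in all 4 of these fits. For the 7 classes with 0 calls in edgeR, the genes at an unadjusted p under 0.05 numbered 146 in plasmacytoid dendritic cells, 243 in other T cells, 217 in regulatory T cells, 195 in NK cells, 634 in cycling tumour cells, 282 in fibroblasts and 208 in endothelial cells. DESeq2 called 0, 0, 0, 0, 5, 2 and 1 genes in these classes. The counts without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2 were 0, 26, 7 and 48 in plasmacytoid dendritic cells, and 0, 19, 1 and 5 in other T cells. In regulatory T cells they were 6, 14, 12 and 10, in NK cells 29, 24, 58 and 8, and in cycling tumour cells 13, 7, 62 and 82. Fibroblasts had 0, 0, 23 and 8, and endothelial cells 8, 5, 44 and 4.

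Neutrophils, the most frequent class in WT replicate 1 and SAA_KO replicate 1, held less RNA of antiviral and heat shock genes in the libraries labelled SAA_KO when summed over their clusters, which differed in size. The interferon-led cluster 19 of this class held 464, 110, 159 and 29 cells (4.37, 1.25, 1.41 and 0.290% of kept cells; edgeR adjusted p = 0.978 for its share). Ifit1, which binds foreign RNA, fell from 79.3 and 75.8 CPM to 24.2 and 14.9 (log2 fold change -1.91, SE 0.20), Rsad2 from 189 and 170 to 69.2 and 42.7 (-1.64, SE 0.19), and Isg15, a ubiquitin-like antiviral protein, from 347 and 404 to 139 and 169 (-1.29, SE 0.16). The heat shock chaperones Hspa1a (199, 85.9, 31.9 and 28.8 CPM; -2.25, SE 0.31) and Hspa1b (177, 117, 32.3 and 21.9 CPM; -2.39, SE 0.22) fell too, as did Ciart, a repressor in the circadian clock (24.2, 12.1, 3.29 and 2.48 CPM; -2.65, SE 0.40). Gla, a lysosomal galactosidase (-1.11), and Ankrd33b (-0.91) also fell; these were named after their values were seen. With Saa2 and Saa3 this makes 10 of 10452 genes, with adjusted p from 5.6e-07 to 0.0363 (edgeR quasi-likelihood, Benjamini-Hochberg; DESeq2 called 14, and not Hspa1a, adjusted p = 0.112). The list of dissociation stress, to which the chaperones belong, was lower in this class (23 of 25 members below 0; limma camera adjusted p = 6.2e-11, 0.880 with an estimated correlation), with 2 members past the threshold over all genes and 3 adjusted over the list alone. Of the 11 fixed myeloid genes 0 passed, among them Cd274, which encodes the checkpoint ligand PD-L1 (305, 240, 197.6 and 211 CPM; log2 fold change -0.42, and -0.23 without WT replicate 1), Ptgs2, a prostaglandin synthase (1680, 2655, 1675 and 1630; -0.39), and Il1b (8966, 14730, 8968 and 10690; -0.27). The Ptgs2 value was -0.03 without WT replicate 2 and -0.68 without WT replicate 1. That of Il1b was 0.13 without WT replicate 2, -0.58 without WT replicate 1 and -0.14 without SAA_KO replicate 1. Without the interferon-led clusters, an alternative chosen after seeing the data, Saa2 and Saa3 alone passed, with Ifit1 at -1.12 (SE 0.53), Rsad2 at -0.89 (SE 0.19), Isg15 at -1.01 (SE 0.22), Hspa1a at -0.33 (SE 0.29), Hspa1b at -0.66 (SE 0.23) and Ciart at -1.13 (SE 0.49), so most of the fall of the 2 chaperones went with those clusters. Without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2 the counts were 17, 57, 113 and 76, and without WT replicate 1 Ciart was lost (-1.99, edgeR adjusted p = 0.438) and Hspa1a stood at -1.48.

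In monocyte-macrophage cells, 4 of 12737 genes passed, 2 higher and 2 lower in the libraries labelled SAA_KO. Irf7, the master regulator of the type I interferon response, fell from 74.1 and 73.8 CPM to 30.99 and 30.07 (log2 fold change -1.28, SE 0.09), and Mid1, a ubiquitin ligase of microtubules, from 21.7 and 22.6 to 7.53 and 8.58 (-1.45, SE 0.13). Hddc3, a metal-dependent hydrolase, rose with Saa2, from 1.34 and 2.55 CPM to 14.8 and 13.5 (2.84, SE 0.26). Of the 30 distinct genes called in any class, 4 lie on chromosome 7 (Saa2, Saa3, Hddc3 and Irf7), Hddc3 at 33.6 Mb from Saa2. This count was not set against the share of all tested genes on that chromosome, so it says nothing of a linked effect. The 4 adjusted p ran from 0.00545 to 0.0226 (edgeR quasi-likelihood, Benjamini-Hochberg), and DESeq2 called 30 genes. Rsad2 stood at 61.9, 55.3, 18.9 and 26.2 CPM (-1.37, SE 0.15; edgeR adjusted p = 0.0625) and passed without WT replicate 1 (0.0349), WT replicate 2 (0.0144) or SAA_KO replicate 2 (0.00841). Saa1 stood at 0.0707, 0.191, 1.43 and 2.58 CPM (3.86, SE 0.61; edgeR adjusted p = 0.187). Genes of macrophage state did not pass: Arg1, which depletes arginine, stood at 2119, 1280, 2378 and 1098 CPM (0.03), Nos2, which makes nitric oxide, at 25.01, 5.92, 9.05 and 2.52 (-1.48), and Cxcl10, which draws T cells, at 119, 85.5, 62.3 and 84.7 (-0.47). The Cxcl10 value was -0.21 without WT replicate 1, -0.27 without SAA_KO replicate 1 and -0.71 without SAA_KO replicate 2. The Nos2 value was -0.10 without WT replicate 1, -2.60 without SAA_KO replicate 1 and -0.76 without SAA_KO replicate 2. The Arg1 value was -0.63 without SAA_KO replicate 1, -0.29 without WT replicate 2, 0.44 without WT replicate 1 and 0.48 without SAA_KO replicate 2. The counts without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2 were 21, 27, 1 and 12, and without SAA_KO replicate 1 the adjusted p in edgeR was 0.0930 for Irf7, 0.143 for Hddc3 and 0.153 for Mid1.

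Cycling macrophages held less RNA of 2 monocyte-drawing chemokines in the libraries labelled SAA_KO. Ccl12 fell from 355 and 297 CPM to 144 and 135 (log2 fold change -1.22, SE 0.17), Ccl8 from 1051 and 1137 to 628 and 523 (-0.93, SE 0.14), and S100a8, a calprotectin subunit abundant in neutrophils, from 118 and 132 to 38.1 and 12.2 (-2.54, SE 0.32). With Saa2, 4 of 8252 genes passed, with adjusted p up to 0.0167 (edgeR quasi-likelihood, Benjamini-Hochberg; DESeq2 called 3, and not S100a8, adjusted p = 0.9997), and 0, 37, 14 and 22 passed without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2. Without WT replicate 1 the 4 adjusted p in edgeR were 0.993. The fixed list of neutrophil genes, kept as a sign of free RNA, was lower in this class (4 of 5 members below 0; limma camera adjusted p = 2.3e-05, 0.880 with an estimated correlation), and S100a8 is one of its members. MHC class II genes, which present antigen to CD4 T cells, were higher as a list in cycling macrophages (10 of 10 members above 0, median log2 fold change 0.41; limma camera adjusted p = 3.9e-12, 0.880 with an estimated correlation). That list was higher in 5 of 18 fits and lower in 1, mature dendritic cells. Of the higher shifts, that in cycling macrophages alone held without any 1 library. Those in NK and other T cells turned lower without SAA_KO replicate 2. Ribosomal protein genes (36 of 41 above 0; camera adjusted p = 0.00070) and mitochondrial transcripts (12 of 13; 0.00161) were higher in the same cells, each at 0.880 with an estimated correlation. The first did not pass without SAA_KO replicate 2 (0.914), nor the second without WT replicate 2 (0.235) or SAA_KO replicate 1 (0.0534). Of the MHC class II genes, 6 passed adjusted over the list alone and 0 over all genes. H2-Aa stood at 0.48 (0.72 without WT replicate 2 and 0.27 without WT replicate 1).

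Of the dendritic classes, cDC1 cells alone had interferon genes past the threshold with all 4 libraries, and the difference between these classes was not tested. In cDC1 cells, which cross-present antigen to CD8 T cells, Isg15 fell from 144 and 106 CPM to 25.8 and 32.7 (log2 fold change -2.01, SE 0.22) and Irf7 from 66.7 and 55.2 to 23.7 and 14.6 (-1.68, SE 0.27). S100a9, the other calprotectin subunit, rose from 45.0 and 60.6 to 190 and 168 (1.68, SE 0.18), beside a list of neutrophil genes that was higher in this class (4 of 5 members above 0; limma camera adjusted p = 6.3e-07, 0.880 with an estimated correlation). With Saa2, 4 of 8189 genes passed, with adjusted p up to 0.0206 (edgeR quasi-likelihood, Benjamini-Hochberg; DESeq2 called 3, and not Irf7, adjusted p = 0.293), each in edgeR also without any 1 library. Cxcl9, which draws T cells, stood at 570, 229, 195 and 231 CPM in cDC1 cells (-0.84), and passed without WT replicate 2 (-1.41, edgeR adjusted p = 1.2e-12) or SAA_KO replicate 2 (-0.99, 0.00112). Without WT replicate 1 it stood at -0.10 (edgeR adjusted p = 0.9997), so the fall rests on that library. Ccl22 stood there at 55.8, 59.1, 76.2 and 100 (0.62, and 0.39 without SAA_KO replicate 2). In mature dendritic cells, Ccl24, an eosinophil-drawing chemokine of macrophages, fell from 126 and 304 CPM to 29.7 and 29.6 (-2.86, SE 0.35; edgeR adjusted p = 0.00219). DESeq2 called 0 genes there, with an adjusted p of 0.0708 for Ccl24. Suppressive macrophage genes, of which Ccl24 is a member, were lower as a list in this class (10 of 15 members below 0; limma camera adjusted p = 0.00161), as were complement and scavenger genes (7 of 10; 0.0347, and 0.782 without WT replicate 1), each at 0.880 with an estimated correlation. MHC class II genes were lower there (11 of 12 members below 0, median -0.23; limma camera adjusted p = 6.2e-06, 0.880 with an estimated correlation), but not without SAA_KO replicate 1 (0.361). Ribosomal protein genes (0.00617, and 0.1597 without WT replicate 1) and mitochondrial transcripts (0.00468, 0.617 without WT replicate 1 and 0.280 without SAA_KO replicate 2) were lower in mature dendritic cells too, and neutrophil genes higher (1.0e-05), each by camera and at 0.880 with an estimated correlation. Il12b, the p40 subunit of interleukin-12, stood in mature dendritic cells at 227, 153, 143 and 59.2 CPM (-0.96) and passed without WT replicate 2 (-1.22, edgeR adjusted p = 0.0227) or SAA_KO replicate 1 (-1.67, 1.1e-06), but was -0.41 without SAA_KO replicate 2 (edgeR adjusted p = 0.9365) and -0.65 without WT replicate 1 (0.7806). Ccr7, the receptor for migration to lymph nodes, stood at 2112, 2108, 2289 and 2068 (0.05, and -0.03 without SAA_KO replicate 1). In cDC2 cells Saa2 alone passed of 8993 genes in edgeR, and DESeq2 called 0. Hddc3 (0.846, 2.55, 18.7 and 13.96 CPM; 2.98) and Isg15 (197.97, 117, 68.3 and 70.3 CPM; -1.15) passed there without WT replicate 2 (4.10, edgeR adjusted p = 0.0164, and -1.51, 7.3e-08), and Isg15 was -0.76 without WT replicate 1. Without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2, the counts were 33, 42, 17 and 35 in cDC1 cells, 4, 36, 1 and 2 in cDC2 cells, and 23, 23, 17 and 42 in mature dendritic cells.

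In CD8 T cells 8 of 7029 genes passed, 1 higher and 7 lower in the libraries labelled SAA_KO. Gzmc, a granzyme of strongly activated killer cells, fell from 78.9 and 63.0 CPM to 17.7 and 5.89 (log2 fold change -2.76, SE 0.40), and Cd4, the coreceptor of helper cells, from 337 and 207 to 123 and 109 (-1.21, SE 0.20). Il1b (122, 140, 51.6 and 61.5 CPM; -1.20, SE 0.21) and Ccrl2 (70.7, 81.0, 30.6 and 22.7 CPM; -1.57, SE 0.29), genes of myeloid cells, fell, and so did Hspa1a (46.3, 30.6, 4.84 and 9.26 CPM; -2.25, SE 0.45). S100a8, abundant in neutrophils, rose from 2.72 and 10.8 to 37.1 and 65.7 (2.82, SE 0.49). Keratins were higher as a list in this class (6 of 6 members above 0; limma camera adjusted p = 0.00978, 0.880 with an estimated correlation), but not without WT replicate 1 (0.497) or SAA_KO replicate 2 (0.729). Ribosomal protein genes were lower (39 of 41 below 0; camera adjusted p = 0.00047, 0.880 with an estimated correlation), but not without WT replicate 1 (0.628). Immunoglobulin genes were lower (4 of 5 below 0; camera adjusted p = 0.00768, 0.880 with an estimated correlation), but not without WT replicate 1 (0.658), SAA_KO replicate 1 (0.132) or SAA_KO replicate 2 (0.196). Gm156 (-1.03) and Fcer1g (-1.12), named after their values were seen, also fell. The 8 adjusted p ran from 0.00258 to 0.0418 (edgeR quasi-likelihood, Benjamini-Hochberg), and DESeq2 called 0. Other genes of the class did not pass: Cd8a stood at 778, 916, 1093 and 1118 CPM (0.38), Gzmb, the main granzyme of killing, at 144, 104, 160 and 238 (0.74), Prf1, which forms the pores, at 286, 304, 190 and 205 (-0.57), Ifng at 201, 171, 200 and 210 (0.16, 0.03 without WT replicate 2 and 0.27 without WT replicate 1), and Pdcd1, which encodes PD-1, at 476, 488, 472 and 472 (-0.03). Gzmb passed without WT replicate 1 (0.97, edgeR adjusted p = 0.0455) or SAA_KO replicate 1 (0.97, 0.0240), but was 0.39 without SAA_KO replicate 2 (edgeR adjusted p = 0.9995) and 0.50 without WT replicate 2 (0.718). The chemokine Ccl5 (0.80) stood at 1.16 without WT replicate 2, 0.87 without SAA_KO replicate 2 and 0.52 without WT replicate 1. Ccl4 (0.65) stood at 0.79 without WT replicate 2 and 0.52 without WT replicate 1. Gzmc and Cd4 held without any 1 library. Hspa1a was lost in each of these 4 fits (edgeR adjusted p = 0.422, 0.184, 0.115 and 0.0533). S100a8 (4.24 without WT replicate 2) was lost without SAA_KO replicate 2 (0.364), Ccrl2 without WT replicate 2 (0.189) or SAA_KO replicate 2 (0.116), Il1b without WT replicate 2 (0.184), Gm156 without WT replicate 1 (-0.56, 0.443), and Fcer1g without WT replicate 2 (0.201) or SAA_KO replicate 1 (0.0764), all in edgeR. The counts without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2 were 39, 13, 29 and 24.

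In the other T and NK cells no gene passed in edgeR or DESeq2, and the genes below are given as values. In other T cells Xcl1, which draws cDC1 cells, had the smallest p and stood at 212, 93.9, 52.1 and 42.1 CPM (log2 fold change -1.66, SE 0.33; -1.01 without WT replicate 1, and past the threshold without WT replicate 2, edgeR adjusted p = 3.4e-12), Isg15 stood at 81.02, 86.05, 24.04 and 39.49 (-1.34, SE 0.29) and Ifit1 at 51.8, 76.7, 12.02 and 28.96 (-1.57, SE 0.37; -2.44 without SAA_KO replicate 2). In regulatory T cells the smallest p belonged to Gm43305 (18.2, 33.2, 123 and 65.3 CPM; 1.77, SE 0.37) and Col1a2, a collagen of fibroblasts (18.2, 31.2, 58.7 and 108 CPM; 1.69, SE 0.38). Gm43305 passed without WT replicate 2 (edgeR adjusted p = 0.00541) or SAA_KO replicate 2 (3.9e-05), and Col1a2 without WT replicate 2 (0.0208) or SAA_KO replicate 1 (0.00021). Foxp3, which defines this class, stood at 494, 557, 515 and 422 CPM (-0.17, from -0.32 without SAA_KO replicate 1 to -0.04 without SAA_KO replicate 2, and -0.08 without WT replicate 2). In NK cells the smallest p belonged to Ctss (110, 74.4, 151 and 605 CPM; 2.13, SE 0.41) and Tmem176b (66.0, 21.9, 122 and 211 CPM; 1.99, SE 0.43), genes abundant in myeloid cells. Ctss passed without WT replicate 1, WT replicate 2 or SAA_KO replicate 1 and was 0.68 without SAA_KO replicate 2, and Tmem176b passed without WT replicate 1 or SAA_KO replicate 1. In the same cells Ifng, the cytokine that activates macrophages, stood at 74.8, 83.2, 18.8 and 33.6 CPM (-1.45, SE 0.52) and Xcl1 at 1126, 919, 480 and 533 (-1.01, SE 0.22; edgeR adjusted p = 0.106). Xcl1 passed without SAA_KO replicate 1 (edgeR adjusted p = 0.0081) or SAA_KO replicate 2 (0.0224). The cytotoxicity and activation list was lower in NK cells (17 of 18 members below 0, median -0.40; limma camera adjusted p = 2.3e-05, 0.880 with an estimated correlation), with 2 members past the threshold adjusted over the list alone and 0 over all genes. Ribosomal protein genes were lower in NK cells too (36 of 41 below 0; limma camera adjusted p = 0.00392, 0.880 with an estimated correlation), but not without WT replicate 1 (0.725), as were oxidative phosphorylation genes (0.00355 by camera, 0.880 with an estimated correlation), but not without WT replicate 2 (0.230) or SAA_KO replicate 1 (0.132). MHC class II genes were higher in NK cells (7 of 7 members above 0; limma camera adjusted p = 1.7e-07, 0.880 with an estimated correlation). That shift rests on SAA_KO replicate 2, where Cd74 stood at 3130 CPM (229, 254 and 197.6 in the others) and H2-Aa at 1176 (110, 91.9 and 84.7). Without it Cd74 stood at -0.31 and H2-Aa at -0.27, and the list lay lower (camera adjusted p = 0.798).

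B cells of the libraries labelled SAA_KO held more RNA of a chemokine and less of genes abundant in tumour cells and macrophages. Ccl4, which draws T cells and monocytes, rose from 10.5 and 12.5 CPM to 248 and 306 (log2 fold change 4.505, SE 0.38). Clu (1678, 2353, 407 and 509 CPM; -2.14, SE 0.23), Spp1 (1532, 2007, 384 and 514 CPM; -1.98, SE 0.23) and Cp, the copper carrier ceruloplasmin (110, 147, 9.37 and 14.1 CPM; -3.42, SE 0.47), fell. These were 4 of 3822 genes, with adjusted p from 0.00167 to 0.0298 (edgeR quasi-likelihood, Benjamini-Hochberg; DESeq2 called 5, and not Cp, adjusted p = 0.0765). S100a8 stood at 15.7, 31.2, 286 and 141 CPM (3.06, SE 0.47; edgeR adjusted p = 0.0626), and passed without WT replicate 2 (2.7e-06), SAA_KO replicate 1 (0.000327) or SAA_KO replicate 2 (7.5e-14). The list of epithelial genes was lower in B cells too (5 of 5 members below 0; limma camera adjusted p = 5.0e-07, 0.880 with an estimated correlation). Without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2, 0, 33, 54 and 62 genes passed, and without WT replicate 1 the 4 adjusted p in edgeR were 0.910. In plasma cells, which secrete antibody, the light chain segment Igkv3-12 stood at 38.7 and 40.1 CPM in the libraries labelled WT and at 0 in both labelled SAA_KO, at least 38.8-fold lower at 3 counts per library (edgeR adjusted p = 0.00858). It was the only 1 of 8859 genes to pass (DESeq2 called 5), and did so without any 1 library. Igkv5-43 stood there at 35.4, 17.4, 104 and 79.6 CPM (1.87, SE 0.32). The counts in plasma cells without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2 were 5, 8, 4 and 5.

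In tumour cells 1 of 14801 genes passed in edgeR, and DESeq2 called 21. Tff3 fell from 17.4 and 18.5 CPM in the libraries labelled WT to 3.71 and 4.03 in those labelled SAA_KO (log2 fold change -2.21, SE 0.11; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00479, and 0.0725 without WT replicate 1). Adm, a vasodilator peptide that low oxygen switches on, stood at 17.8, 14.4, 5.85 and 3.18 CPM (-1.82, SE 0.26; edgeR adjusted p = 0.881), and passed without SAA_KO replicate 1 (-2.34, 1.7e-05) or SAA_KO replicate 2 (-1.46, 0.000483). H2-K1 and B2m, of antigen presentation, and Cd274 were highest in SAA_KO replicate 2: H2-K1 stood at 899, 889, 867 and 1281 CPM (0.26, and -0.04 without that library), B2m at 1042, 1009, 1021 and 1546 (0.32, and -0.005 without it) and Cd274 at 7.49, 5.81, 6.51 and 8.88 (0.21, and -0.03 without it). Ptgs2 stood at 69.5, 62.1, 44.6 and 57.4 CPM (-0.37, -0.20 without SAA_KO replicate 1 and -0.56 without SAA_KO replicate 2). In cycling tumour cells Agr2, a chaperone of mucus secretion, stood at 73.8, 61.4, 33.7 and 31.1 CPM (-1.06, SE 0.11) and S100a9 at 16.7, 17.98, 32.1 and 37.9 (1.01, SE 0.11), each with an edgeR adjusted p of 0.133. Without WT replicate 1, WT replicate 2, SAA_KO replicate 1 and SAA_KO replicate 2, Agr2 stood at -0.92, -1.187, -1.124 and -1.002. S100a9 stood at 0.9624, 1.068, 1.122 and 0.89 without the same libraries. Neutrophil genes, the sign of free RNA, were higher in cycling tumour cells too (6 of 8 members above 0; limma camera adjusted p = 0.0224, 0.880 with an estimated correlation, 0.168 without WT replicate 2). The counts in tumour cells without these libraries in turn were 0, 3, 52 and 73.

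Stromal cells had no gene past the threshold in edgeR, while DESeq2 called 2 in fibroblasts and 1 in endothelial cells. In fibroblasts, Il6, an inflammatory cytokine, stood at 48.8, 62.8, 28.5 and 32.8 CPM (log2 fold change -0.88, SE 0.18), Col1a1, the main collagen, at 12130, 9706, 13410 and 13040 (0.28, SE 0.14; 0.45 without WT replicate 1 and 0.12 without WT replicate 2) and Hddc3 at 8.49, 5.83, 22.04 and 30.8 (1.97, SE 0.29), which passed without SAA_KO replicate 1 (edgeR adjusted p = 0.00367). The collagen and matrix list was higher in fibroblasts (25 of 29 members above 0, median 0.17, limma camera adjusted p = 4.5e-05, 0.880 with an estimated correlation). In the same fibroblasts ribosomal protein genes (camera adjusted p = 0.0307) and dissociation stress genes (0.0364) were lower, and immunoglobulin genes (0.0196) higher. None of these passed with an estimated correlation. Epithelial genes were lower in them (11 of 11 members below 0, median -0.95; limma camera adjusted p = 3.1e-11, 0.880 with an estimated correlation), 7 of them past the threshold adjusted over the list alone and 0 over all genes. Krt8 stood at 71.7, 67.4, 48.4 and 31.9 CPM (-0.81) and Krt19 at 74.3, 64.6, 35.9 and 35.8 (-0.95). The Krt8 value was -1.12 without SAA_KO replicate 1, -0.53 without SAA_KO replicate 2 and 0.16 with predicted doublets kept. In endothelial cells, Acta2, an actin of smooth muscle, stood at 7.12, 20.7, 165 and 125 CPM (3.39, SE 0.38; edgeR adjusted p = 0.0880). Its value ran from 2.805 without WT replicate 1 to 4.305 without WT replicate 2. Il1b stood there at 186.5, 273, 98.4 and 89.2 (-1.29, SE 0.24).

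Genes of the type I interferon response, the antiviral programme, were lower as a group across the tumours labelled SAA_KO. The list of 30 genes was lower in 13 of 18 fits (17 classes and the sums over all cells) by limma camera with a preset correlation, and higher in 0. With an estimated correlation the adjusted p was 0.880 in each of the 13 fits. Its median log2 fold change was below 0 in each of the 18. In monocyte-macrophage cells 28 of 28 tested members lay below 0 (median -0.72; camera adjusted p = 1.7e-60), in neutrophils 25 of 25 (-0.87; 1.4e-40), in cycling macrophages 20 of 21 (-0.70; 1.6e-16), in cDC2 cells 23 of 24 (-0.56; 1.6e-16), in fibroblasts 25 of 25 (-0.51; 1.8e-14), in cDC1 cells 15 of 16 (-0.70; 1.3e-13), in other T cells 18 of 20 (-0.53; 5.9e-12) and in mature dendritic cells 14 of 16 (-0.70; 6.7e-10). Over all fits 6 members passed over all genes tested, and 99 adjusted over the list alone, 26 of these in monocyte-macrophage cells and 19 in neutrophils. Summed over the list, the transcripts stood at 2079, 2317, 1281 and 1517 CPM in monocyte-macrophage cells, at 2758, 2718, 1923 and 1664 in neutrophils, and at 948, 993, 849 and 1009 in CD8 T cells. In cycling tumour cells, 1 of the 13 fits, the sum was not lower (459.5, 444.6, 383.3 and 541.1 CPM). In tumour cells the list (21 of 28 members below 0, median -0.46; camera adjusted p = 6.1e-05) was lost without SAA_KO replicate 1 (0.105). It was lost without WT replicate 1 or SAA_KO replicate 1 in endothelial and plasmacytoid dendritic cells, and without WT replicate 2 or SAA_KO replicate 1 in cycling tumour cells.

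**Figure D4:**
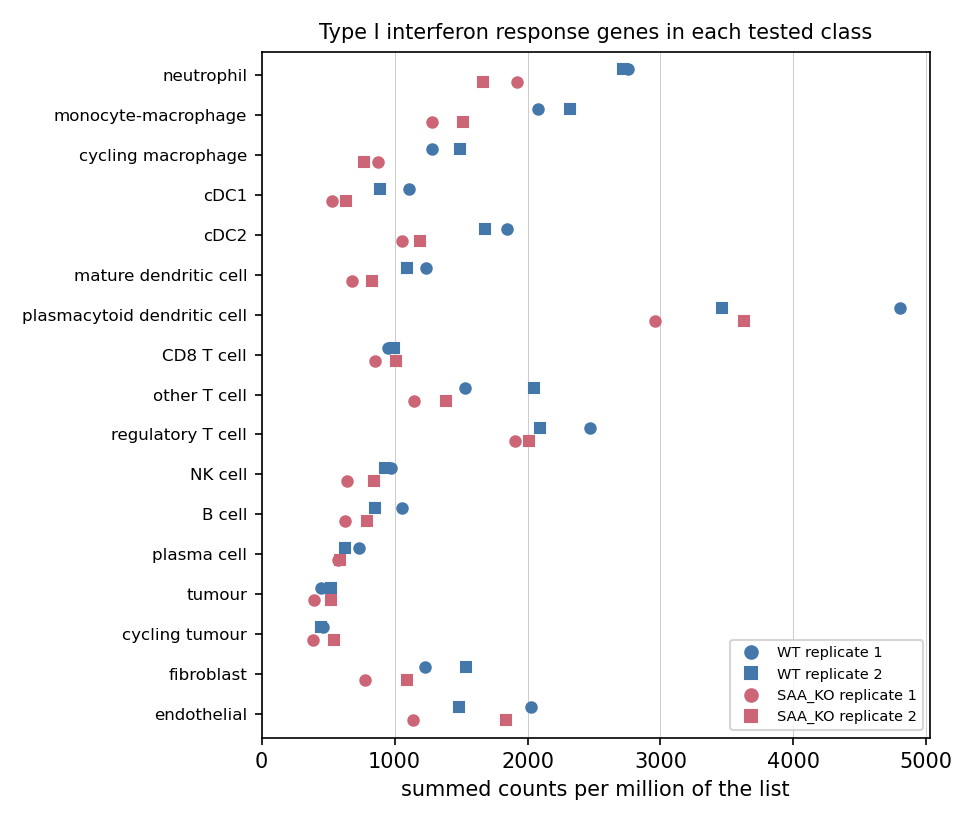
CPM summed over the genes of the type I interferon list in each of the 17 tested cell classes, 1 point per library. Monocyte-macrophage cells lie at 2079 and 2317 in the libraries labelled WT and at 1281 and 1517 in those labelled SAA_KO, and the groups overlap in plasmacytoid dendritic, CD8 T, tumour, cycling tumour and endothelial cells; CD8 T cells lie at 947.7 and 992.8 (WT) and at 848.7 and 1009 (SAA_KO).

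Genes of hypoxia and glycolysis, which cells raise when oxygen is short, were lower in 11 of 18 fits, 5 of which held without any 1 library, and higher in 1, plasmacytoid dendritic cells, by limma camera. With an estimated correlation the adjusted p was 0.880 in each of these 12. In tumour cells 29 of 29 members lay below 0 (median log2 fold change -0.26, camera adjusted p = 1.8e-19), with Ldha, which makes lactate, at -0.18. That Ldha value was -0.08 without WT replicate 2 and -0.28 without WT replicate 1. In neutrophils 28 of 29 lay below 0 (-0.34, camera adjusted p = 1.4e-16), with Ldha at -0.39. The sums over all cells had 29 of 29 members below 0 (-0.20; 3.6e-15), and cycling tumour cells 26 of 29 (-0.14; 5.7e-07). No member passed over all genes tested in edgeR, and 6 passed adjusted over the list alone, 5 of them in tumour cells.

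Antigen presentation genes were higher as lists in tumour cells, with SAA_KO replicate 2 apart from the other libraries. Of the MHC class I genes, which display peptides to CD8 T cells, 19 of 20 lay above 0 (median log2 fold change 0.40; limma camera adjusted p = 1.1e-14), and of the interferon gamma response 26 of 29 (0.40; 5.4e-13). With an estimated correlation, adjusted p = 0.880 for both. The interferon gamma list was lower in fibroblasts (23 of 26 members below 0, median -0.40; camera adjusted p = 2.1e-07, 0.165 without SAA_KO replicate 1) and in other T cells (16 of 21; 0.0224), where it passed without WT replicate 2 alone (0.0478; 0.0868, 0.103 and 0.0586 without WT replicate 1, SAA_KO replicate 1 and SAA_KO replicate 2). The MHC class I list was lower in plasmacytoid dendritic cells (13 of 16; 0.0110, and 0.725 without WT replicate 1) and cDC1 cells (17 of 20; 0.0316, 0.824 without WT replicate 1 and 0.0949 without SAA_KO replicate 1). Each of these 4 stood at 0.880 with an estimated correlation. Without SAA_KO replicate 2 the medians in tumour cells fell to 0.132 (14 of 20 above 0; camera adjusted p = 0.00018) and 0.0938 (20 of 29; 0.0029), and H2-K1 and B2m stood at -0.04 and -0.005. Adjusted over the list alone 8 and 2 members passed, and 0 over all genes. In cycling tumour cells 19 of 20 MHC class I genes lay above 0 (camera adjusted p = 7.0e-10, 0.880 with an estimated correlation), and the interferon gamma list (29 of 29; 1.1e-10) was lost without SAA_KO replicate 2 (0.798). Cell cycle genes were higher in tumour cells (31 of 34 above 0, median 0.20, camera adjusted p = 2.9e-10, 0.880 with an estimated correlation). Lists of other cells moved in the same tumour cells: fibroblast genes (camera adjusted p = 0.00355), collagen and matrix (0.00355) and immunoglobulin genes (0.0190) were higher. Ribosomal protein genes (0.0316) were lower there, and none of these passed with an estimated correlation.

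Over all 42 lists, camera with a preset correlation put 148 of 620 pairs of list and fit past 0.05 after Benjamini-Hochberg adjustment, 89 lower and 59 higher, and 39 of them held without any 1 library. With an estimated correlation 0 passed (smallest adjusted p = 0.880, and 12 pairs at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.290, and 34 pairs at an unadjusted p under 0.05). Lists kept as signs of free RNA moved too. By camera, acinar enzymes were lower in 7 fits, neutrophil genes higher in 4 and lower in 1, and immunoglobulin genes higher in 7 and lower in 1. These shifts share fits with the interferon, hypoxia and MHC class I lists: 12 of 12 acinar enzymes lay below 0 in neutrophils (camera adjusted p = 4.7e-07) and in tumour cells (3.0e-06), with an adjusted p of 0.880 for both with an estimated correlation. Without SAA_KO replicate 1, which held few acinar cells, they were higher in neutrophils (0.00237) and not past the threshold in tumour cells (0.610). The fixed receptors of serum amyloid A and interleukin-6 (Tlr2, Tlr4, Fpr1, Fpr2, Il6ra and Il6st) gave 0 genes past the threshold in any class in which they were tested. All 6 were tested in neutrophils, monocyte-macrophage cells and cycling macrophages alone. In the other classes the low-count filter left out some or all of them, with 1 tested in CD8 T and in regulatory T cells.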

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

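Of the tests in this part, that of a single effect on the locus and those of free RNA were chosen only after the Saa3 result was seen. Saa3 was singled out because its fold change, SAA_KO over WT by the labels, differed between neutrophils and monocyte-macrophage cells by 4.06 on the log2 scale (SE 0.21, n = 2 libraries per group), in a test of the difference itself. Free RNA gives a like number of molecules per droplet, and acinar enzymes, kept as its sign, stood per cell at up to 0.715 times the tumour class in monocyte-macrophage cells and 0.406 times in neutrophils of the libraries labelled SAA_KO. Saa3 UMIs per monocyte-macrophage cell were at least 10.25 times those per tumour cell in each of the 4 libraries (lowest bound of the 95% counting intervals 8.28). Those per neutrophil were 6.34 and 7.27 times in the libraries labelled SAA_KO (lowest bound 5.13), and 0.702 times in both labelled WT. These ratios argue against free RNA as the source in monocyte-macrophage cells, and in neutrophils of the libraries labelled SAA_KO. A change in the mix of clusters needs fold changes near 0 inside clusters, while their median was -1.75 over the monocyte-macrophage clusters and 1.71 over the neutrophil clusters. A single effect of an engineered locus on its neighbour in all host cells, of the same direction in both classes, cannot be told apart: the difference of 4.06 is what Saa3 was picked for, and the value in monocyte-macrophage cells alone did not pass. As a hypothesis, the host genotype may act on Saa3 in a different direction in each class, which was not tested. Since the Saa2 counts leave the labels unchecked, which genotype is higher is open.

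Ins2, Ins1 and Gla also differed between both classes, by 5.95, 5.78 and -0.96 on the log2 scale, in the same test. The insulin genes stood at 5.47 UMIs per monocyte-macrophage cell in WT replicate 2 and at most at 0.0228 in the other libraries, so their difference rests on that library.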

How the results depend on the processing

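The alternatives leave most directions of single genes in place and move the counts, and the cause was not tested for any of them unless named. Some lists turned direction without 1 library, among them acinar enzymes in neutrophils and MHC class II genes in NK cells. Those chosen after seeing the data are automatic doublet thresholds, shared barcodes left out and interferon-led clusters left out. Leaving out 1 library keeps a lone library in its group, which is assumed to vary like the others. Such fits called more genes within classes than all 4 libraries together, so a call kept or gained in them is weak support. The 39 calls within classes became 89 with DESeq2's Wald test (24 of the 39 also called), 759 with no filter on low counts, 70 with predicted doublets kept, 61 with automatic doublet thresholds, and 2.0e+02 to 518 without 1 library. DESeq2 size factors gave 39, a higher Leiden resolution 44, a stricter cell filter 55, shared barcodes left out 58, one adjustment over all classes 30, and interferon-led clusters left out 31. The 0 genes of the sums over all cells (edgeR; 340 at an unadjusted p under 0.05) became 28 with DESeq2's Wald test, 1 without shared barcodes and 0 to 2 without 1 library. In neutrophils the 10 calls became 84 with no filter, 2 without interferon-led clusters and 17 to 113 without 1 library. In monocyte-macrophage cells the 4 became 30 with the Wald test, 157 with no filter and 1 to 27 without 1 library. In CD8 T cells the 8 became 0 with the Wald test, 37 with no filter, 5 without shared barcodes and 13 to 39 without 1 library. In tumour cells the 1 became 21 with the Wald test, 15 with no filter, 0 with the stricter cell filter and 0 to 73 without 1 library. In the other 13 classes the 16 calls became 24 with the Wald test, 466 with no filter, 48 with predicted doublets kept, 42 with automatic doublet thresholds, 38 without shared barcodes, 28 with the stricter cell filter and 121 to 333 without 1 library.

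The 148 list shifts became 0 with an estimated correlation and 0 with fry (smallest adjusted p = 0.880 and 0.290), and 155 to 240 without 1 library. The 13 fits with a lower type I interferon list became 0 with an estimated correlation and 0 with fry, and 9 to 15 without 1 library. The 26 calls of genes in lists became 64 with the Wald test, 322 with no filter, 41 with the stricter cell filter, 44 with predicted doublets kept, 41 with automatic doublet thresholds, 40 without shared barcodes and 93 to 243 without 1 library. The 0 classes with a changed share became 0 to 1 without 1 library.

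The labels give both groups the same replicate numbers and say nothing of a shared day or litter, so the libraries were not taken as pairs. A shared day is not excluded: same-numbered libraries deviated with correlations of -0.016 to 0.319, over 0.1 in 10 of 18 fits. Neutrophil shares went with the number (29.7 and 32.1% for replicate 1, 16.4 and 13.2% for replicate 2). So did the median UMIs per kept cell (3225.5 and 2574, against 5019.5 and 4317). Regulatory T cell shares did not (1.34 and 1.59%, against 2.10 and 1.36%). Both replicates 1 shared 152 barcodes, other pairs of libraries 41 to 48. With the replicate number as a block, the calls within classes numbered 418, in the sums over all cells 5, in neutrophils 167, in monocyte-macrophage cells 58, in CD8 T cells 61, in the other 13 classes 131, and among genes in lists 195; Arg1 in monocyte-macrophage cells stood at -0.027 with this block.

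Of 106 values of single genes under 1477 alternatives, 1228 kept direction and side of the threshold, 71 lost the call, 164 gained it and 14 reversed. Without 1 library, the log2 fold change ran from -0.58 to 0.13 for Il1b in neutrophils, -0.63 to 0.48 for Arg1, -2.60 to -0.10 for Nos2, -7.63 to 1.01 for Ins2 and -7.76 to 1.72 for Ins1 in monocyte-macrophage cells, -0.0255 to 0.11 for Ccr7 in mature dendritic cells, -0.31 to 3.68 for Cd74 and -0.27 to 3.52 for H2-Aa in NK cells, and in tumour cells -0.044 to 0.52 for H2-K1, -0.0046 to 0.59 for B2m and -0.032 to 0.41 for Cd274. Pdcd1 in CD8 T cells was 0.0021 with no filter on low counts, and Krt8 in fibroblasts 0.16 with predicted doublets kept. What depth limits in the smallest classes was not simulated: plasmacytoid dendritic cells held 32, 34, 27 and 28 cells and had 2784 genes tested, against 12737 in monocyte-macrophage cells.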

Other observations

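The tests in this part on Saa2, and the test of interferon-led clusters for the called neutrophil genes, were chosen only after the results were seen, as were the interferon-led clusters themselves. In neutrophils of the libraries labelled SAA_KO, the NF-kB and TNF response, the core inflammatory programme, was lower as a list (26 of 27 members below 0, median log2 fold change -0.27; limma camera adjusted p = 2.8e-06, 0.880 with an estimated correlation). In the same neutrophils the list of dissociation stress (6.2e-11) and acinar enzymes (4.7e-07; higher without SAA_KO replicate 1, 0.00237) were lower and immunoglobulin genes higher (0.00085; 0.273 without WT replicate 1), each by camera and at 0.880 with an estimated correlation. In CD8 T cells the exhaustion list, genes of cells under lasting stimulation, was higher (10 of 16 members above 0, median 0.07; camera adjusted p = 0.0250, 0.880 with an estimated correlation), with 4 members higher and 1 lower adjusted over the list alone and 0 over all genes. Ribosomal protein genes were lower in these cells (camera adjusted p = 0.00047, 0.628 without WT replicate 1, 0.880 with an estimated correlation). In endothelial cells the angiogenesis list was lower (18 of 20 members below 0, median -0.17; camera adjusted p = 5.9e-06, 0.880 with an estimated correlation). In the same cells mitochondrial transcripts were lower (camera adjusted p = 3.1e-07), and neutrophil genes (0.00204), epithelial genes (0.00399) and keratins (0.0162) higher, each at 0.880 with an estimated correlation. These were lost without SAA_KO replicate 2 (mitochondrial transcripts 0.621, epithelial genes 0.346, keratins 0.239) or WT replicate 1 (neutrophil genes 0.146, epithelial genes 0.579, keratins 0.965). In B cells 41 of 41 ribosomal protein genes lay below 0 (median -0.22; camera adjusted p = 1.9e-14, 0.880 with an estimated correlation). Mitochondrial transcripts (camera adjusted p = 0.00077, and 0.359 without WT replicate 2) and oxidative phosphorylation genes (0.00157, 0.358 without WT replicate 2 and 0.272 without SAA_KO replicate 1) were lower there too, each at 0.880 with an estimated correlation.

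Saa2 was higher in the libraries labelled SAA_KO, and whether this bears on the labels depends on the deleted part, which is unknown. Free RNA gives a like number of molecules per droplet. In the 6 classes in which Saa2 passed, its UMIs per cell were at least 6.35 times those per tumour cell in both libraries labelled SAA_KO (lowest bound of the 95% counting intervals 3.55), while acinar enzymes reached at most 1.13 times, which argues against free RNA as the source in these classes. The same holds for 4 of the other 9 tested host classes, by the lower ratio of both libraries: fibroblasts (18.28, lowest bound 11.45), plasma cells (4.67, 2.58), endothelial cells (3.81, 1.14) and regulatory T cells (3.16, 1.43). Each bound lies above 1 and above the ratio of acinar enzymes in the same class and library. In 5 classes free RNA cannot be told apart, since counting intervals reach these limits: plasmacytoid dendritic cells (1.90), B cells (1.72), CD8 T cells (1.54), other T cells (0.946) and NK cells (0.679). A transcript of the engineered locus made in host cells and not in the implanted line cannot be told apart either: per cell, 13 of 15 tested host classes lay above both tumour classes in both libraries labelled SAA_KO, and NK and other T cells did not. An exchange of the labels of both groups stays open and cannot be told apart, since the 19 Saa2 molecules of the libraries labelled WT fit either reading while the deleted part of the locus is unknown. Reads over the deleted exons, or genotyping of the pools, would decide.

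Type I interferon genes were lower in the libraries labelled SAA_KO. Fewer cells in interferon-led clusters as the whole cause is argued against by the list without them. The larger adjusted p of neutrophils and monocyte-macrophage cells was then 1.8e-16 (limma camera), with medians of -0.54 and -0.63 against -0.87 and -0.72. In monocyte-macrophage cells, 1 library as the cause is argued against by the summed CPM, 2079 and 2317 (WT) against 1281 and 1517 (SAA_KO). There the list was lower in each of the 4 fits without 1 library (largest camera adjusted p 1.2e-45). That p measures the spread over genes, so it does not weigh a library. In tumour, cycling tumour, endothelial and plasmacytoid dendritic cells some fits without 1 library lost the list, so 1 library cannot be told apart there. Both p used the preset correlation, and with an estimated correlation the list passed in neither neutrophils nor monocyte-macrophage cells (adjusted p = 0.880). For the called neutrophil genes, fewer cells in the interferon-led clusters cannot be told apart: without those clusters the median ratio of fold changes was 0.587. Ifit1 went from -1.91 (SE 0.20) to -1.12 (SE 0.53), Rsad2 from -1.64 (SE 0.19) to -0.89 (SE 0.19) and Isg15 from -1.29 (SE 0.16) to -1.01 (SE 0.22). The calls ended through smaller folds and, for Ifit1 and Isg15, a larger error. Free RNA as a part of the fall cannot be told apart either: the fall of the summed CPM in other T cells was 0.657 of that in monocyte-macrophage cells. Acinar and immunoglobulin genes also moved in some of the same fits. Whether free RNA is the whole source in monocyte-macrophage cells cannot be told either, since classes with less RNA went both ways. A like number of molecules per droplet gives a larger CPM fall in cells with less RNA. Other T cells (median 1672, 1746.5, 1373.5 and 1503 UMIs, against 5370, 6267.5, 4748 and 5491.5) fell less, and CD8 T cells stood at 948, 993, 849 and 1009 CPM. Neutrophils, with less RNA too, fell more (2758, 2718, 1923 and 1664 CPM). As a hypothesis, an effect of host genotype may remain, untested against these, and its direction rests on labels that the Saa2 counts leave unchecked.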
